A study of Mus musculus with 38 samples.

How the data were processed

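Total RNA from the striatum of 152-day-old MF1 mice was hybridised to Illumina bead arrays with 25697 probes. The labels put 38 animals in 4 groups, 9 XX female, 8 XX male, 9 XXY male and 12 XY male, and in 2 labelled batches. Each animal also has a sample code that ends in the letter a, the letter b, or both. The labels do not say what the letters stand for. All XX female animals had letter b and all XX male animals had letter a, while the XXY male and XY male groups held both. In these last groups every animal with letter a alone was in labelled batch 1. Every one with letter b alone was in labelled batch 2, so only the animals with both letters separate letter from batch there. The letters were treated as a marker of the array run, because letter a arrays were dimmer than letter b arrays.

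The authors deposited a table of bead signal intensity on a linear scale, per the file headers, with a detection p-value, a bead standard error and a bead number for each probe and array. This table was not normalized between arrays. It holds a signal column for 37 of the 38 animals; the signal of XY male replicate 3 was not analysed here, and only its detection p-values were read. In exactly the 9 columns with both letters the bead numbers included values midway between whole numbers, so these columns appear to hold 2 arrays of the same animal merged before deposit. Each was used as 1 animal. The bead standard errors were not used. The authors also deposited a table of log2 values for 12128 of the probes. The columns of this table shared quantiles, some values were missing, and their medians lay between 8.09 and 8.12. Its scale and centring are not given in the sources used here, apart from limma being named in the submitters' processing notes. The values of the other 3 groups ranked like their own arrays, with Spearman correlations between 0.987 and 1.00. The 8 XX male columns did not. They correlated at 0.062 to 0.073 with their own arrays but at 0.937 or more with each other, so their values appear to be out of register with the probe names. The log2 table was therefore used only as an alternative, and only without XX male animals. Number of columns with per-sample values left unused for want of a sample was 0.

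Signals were background-corrected with the normexp model on negative-control levels inferred from the detection p-values, quantile-normalized between arrays and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value below 0.01 in at least 8 animals were kept, which left 12339 probes. Gene names came from a platform annotation that gave exactly 1 symbol for 11458 probes, several for 0 probes, and no symbol for the remaining 14239 probes of the array. Through Entrez identifiers 11454 of the named probes matched a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. That table was used for names, chromosomes and gene spans only, and no coordinates are given because the array carries no genome build. For each named gene the probe with the highest mean was kept, and each unnamed probe stood for itself. This gave 9455 features, 8444 named genes and 1011 unnamed probes. Of the named genes 285 were X-linked, 1 was Y-linked and 8155 were autosomal. Array values have no count depth. Their precision is limited by the number of arrays and by signal over background, and fold changes of dim probes are understated by the offset.

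Each of the 6 pairwise comparisons was fitted with limma's lmFit and eBayes over all 4 groups, with the labelled batch and the share of arrays with letter b (0, 0.5 or 1, called the run term here) as covariates, and p-values were adjusted with the Benjamini-Hochberg method. A feature changed where the adjusted p was below 0.05. The labels call the animals biological replicates. Group means are unadjusted log2 values with their SD, and differences and SE come from the model. Where a changed feature was detected in fewer than 50% of the animals of the dimmer group, the difference is given as a lower bound. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value of any detected probe. Differences within each labelled batch came from separate fits.

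Before the data were examined, 27 gene lists (sex chromosome genes, striatal and other neuron types, glia, vessels, choroid plexus, blood, hormone response, immediate early genes, stress, mitochondria and ribosome) were fixed, of which 25 had at least 3 tested genes. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusting over all 150 pairs of list and comparison. The share of X-linked genes among changed genes was tested with Fisher's exact test, two-sided. The similarity of the XXY male and XX female differences from XY male was set against 100 draws in which the residuals were permuted across animals, which keeps the shared controls and the correlation between genes. The rule for named genes was also fixed before the data were examined. It takes the 10 highest and 10 lowest log2 differences past the threshold with the same sign in both labelled batches, all measured genes of the escape and Y-linked lists, the 4 members of each other list with the smallest p-values, and Esr1, Esr2, Drd1 and Drd2 where measured. Esr1 and Esr2 had no named probe among the tested features. No named autosomal gene passed the threshold between XX female and XY male, so the planned position of XXY male and XX male animals on such genes had no value. A score over the 100 autosomal genes with the smallest p-values in random parts of the animals, read in the animals left out, was added after seeing the data. Its reference, the residuals permuted across animals, replaced the planned permutation of scores after that permutation was found to share the error of the run adjustment between the parts.

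The model fit was tested on simulated data, made from the real residuals permuted across animals with 200 of 9455 features changed. The camera list test and the covariance of the XXY male and XX female differences were tested on other changes put into such residuals. Normalization, the filter, fry, Fisher's test, the regroupings, the score and the component tests were not tested with simulated changes. The bounds for the tests of chance by regrouping had been entered the wrong way round in the list of predictions and were exchanged after the results were seen, without a change to any value. At a log2 change of 0.5 the model recovered 47.9% of changed features for XXY male against XY male, 20.9% for XX female against XY male, 21.2% for XXY male against XX female, 28.1% for XX male against XY male, 24.1% for XXY male against XX male and 3.6% for XX male against XX female. At a log2 change of 1 the shares, in the same order, were 90.0%, 70.7%, 71.8%, 77.4%, 76.3% and 37.5%. These shares hold for 200 changed features. With fewer changed features the Benjamini-Hochberg cut-off is stricter, so the shares overstate what could be found where few features change. Alternatives covered normalization, the filter, the covariates, subsets of animals by letter and batch, the replicate number as a block, array weights, trend, all probes, and each animal left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.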

Results

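Striatal gene expression was measured in adult mice of 4 kinds that differ in sex chromosomes and gonadal sex: XY males, XXY males, XX males and XX females. XXY is the karyotype of Klinefelter syndrome in men, and the series asks whether the striatum of XXY males is feminized. The analysis held 11 XY males, 9 XXY males, 8 XX males and 9 XX females. Detected probes per array ranged from 10089 to 12392. The 90th percentile of the raw signal ranged from 632 to 938 on letter a arrays and from 1266 to 2209 on letter b arrays. Component 2 of the normalized values, with 15.8% of the variance, lay between 9.57 and 31.3 in all letter a animals and between -23.2 and -10.2 in all letter b animals. The run term itself had 662 features higher and 582 lower in letter b arrays, while the labelled batch had 0 (limma, with 156 at an unadjusted p under 0.05). Among XY and XXY males these terms separate only through the animals with both letters, while XX females and XX males each spanned both batches.

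**Figure D1:**
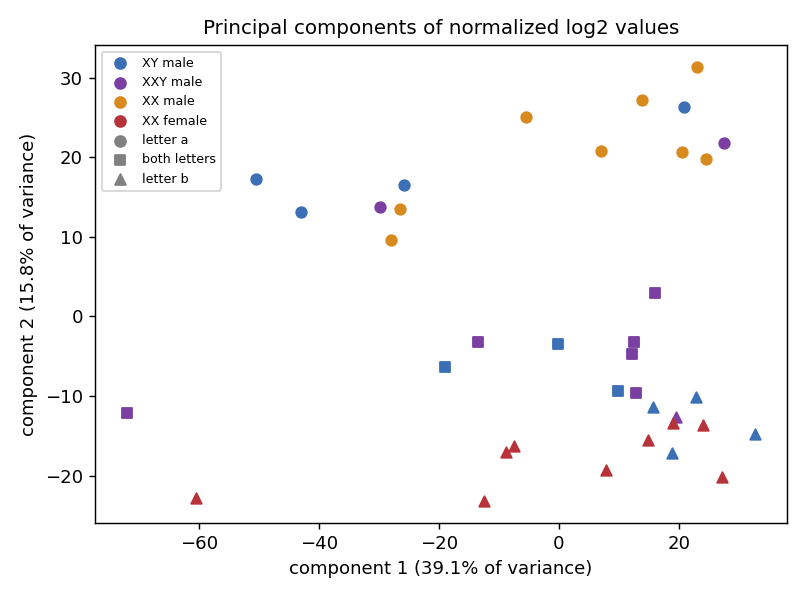
Principal components 1 and 2 of the normalized log2 values of 9455 features, 1 point per animal, with colour for the group and shape for the letter in the sample code. Letter a animals lie at 9.57 or above and letter b animals at -10.2 or below on component 2.

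The labels were checked on the X-inactivation RNA. Xist, the noncoding RNA that coats the inactive X chromosome, was detected in all 9 XX females, all 8 XX males and all 9 XXY males, and in 0 of the 12 XY males with detection p-values. The unnamed probe ILMN_1241001 followed the presence of a Y chromosome, detected in all 12 XY males and all 9 XXY males and in 0 of the 9 XX females and 0 of the 8 XX males. Uty, the only named Y-linked gene tested, stayed near background in every group, at a log2 of 5.58 ± 0.25 (SD, n = 11) in XY males and 5.59 ± 0.33 (SD, n = 9) in XX females, so this probe did not separate animals with and without a Y chromosome.

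The comparison of XXY males with XY males asks what an extra X chromosome does in animals with a Y chromosome. Higher in XXY males were 6 features, and 0 were lower, with 123 at an unadjusted p under 0.05. Xist was at least 5.43-fold higher, with a log2 of 7.91 ± 1.14 (SD, n = 9) in XXY males and 4.67 ± 0.15 (SD, n = 11) in XY males (adjusted p = 1.12e-07). Eif2s3x, the X-linked gene of a translation initiation factor subunit, was 1.50-fold higher (log2 0.58, SE 0.08, adjusted p = 5.14e-05), and all 9 XXY males lay above the XY mean. Its log2 difference was 0.58 in labelled batch 1 and 0.60 in labelled batch 2. The other 4 were unnamed probes. ILMN_3123341 was at least 2.12-fold higher and, like Xist, undetected in XY males (adjusted p = 8.07e-05). ILMN_3159435, detected in 4 of 11 XY males, was at least 2.58-fold higher, at 7.13 ± 0.29 (SD, n = 9) against 5.40 ± 0.69 (SD, n = 11) (adjusted p = 3.23e-06). Among letter a animals, 2 XXY and 4 XY males, its log2 difference was 2.21 (SE 0.35, adjusted p = 0.0983). Letter b held a single XXY male, 0.87 above the 4 XY males, which allows no test. ILMN_2764607 was higher by a log2 of 0.75 (SE 0.13, adjusted p = 0.00208) and ILMN_2944601 by 0.60 (SE 0.11, adjusted p = 0.00991). ILMN_2944601 lost its call in a fit of these 2 groups alone (adjusted p = 0.272).

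Among 7 measured genes of the escape list, Xist included, all 7 had positive differences in XXY males with the probe kept for each. Of these 2 passed over all genes and 4 passed when adjusted over the list alone, namely Xist, Eif2s3x, the histone demethylase gene Kdm6a (log2 0.36, SE 0.10) and Pbdc1 (log2 0.30, SE 0.10). The list rose as a set with the preset and with the estimated correlation (adjusted p = 1.51e-23 and 6.97e-10). Xist, which the karyotype sets in advance, had by far the largest of these differences and weighs on the set test. Of probes not kept, one of Car5b lay at -0.0002 (SE 0.12) and one of Kdm6a at 0.47 (SE 0.12). Ddx3x, at a log2 of 0.22 (SE 0.20), did not pass. Erdr1, the pseudoautosomal gene measured, had a log2 difference of 1.23 (SE 0.36, unadjusted p = 0.00184), which did not pass over all genes (adjusted p = 1.00). The dopamine receptor genes of the 2 striatal output pathways did not pass either, with Drd1 at a log2 of 0.22 (SE 0.19) and Drd2 at 0.12 (SE 0.25). Of 19 striatal projection neuron markers 18 had positive differences, with a median log2 of 0.13. This list passed at the preset correlation (adjusted p = 0.00333) and not with an estimated one (adjusted p = 0.812). Thalamic and septal markers lay the other way, with 1 of 8 positive and a median log2 of -0.50 (adjusted p = 0.000973 and 0.770), as did oligodendrocyte markers with 1 of 11 positive (adjusted p = 0.00703 and 0.770). The 8 choroid plexus markers all had negative differences (median log2 -0.82), among them Otx2 at -0.84 (SE 0.40) and the transthyretin gene Ttr at -0.81 (SE 0.51). Their adjusted p was 1.29e-06 with the preset and 0.768 with the estimated correlation. Microglial genes had 11 of 13 positive differences, for example C1qb at 0.43 (SE 0.20), with adjusted p = 0.00511 and 0.768 in turn.

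**Figure D2:**
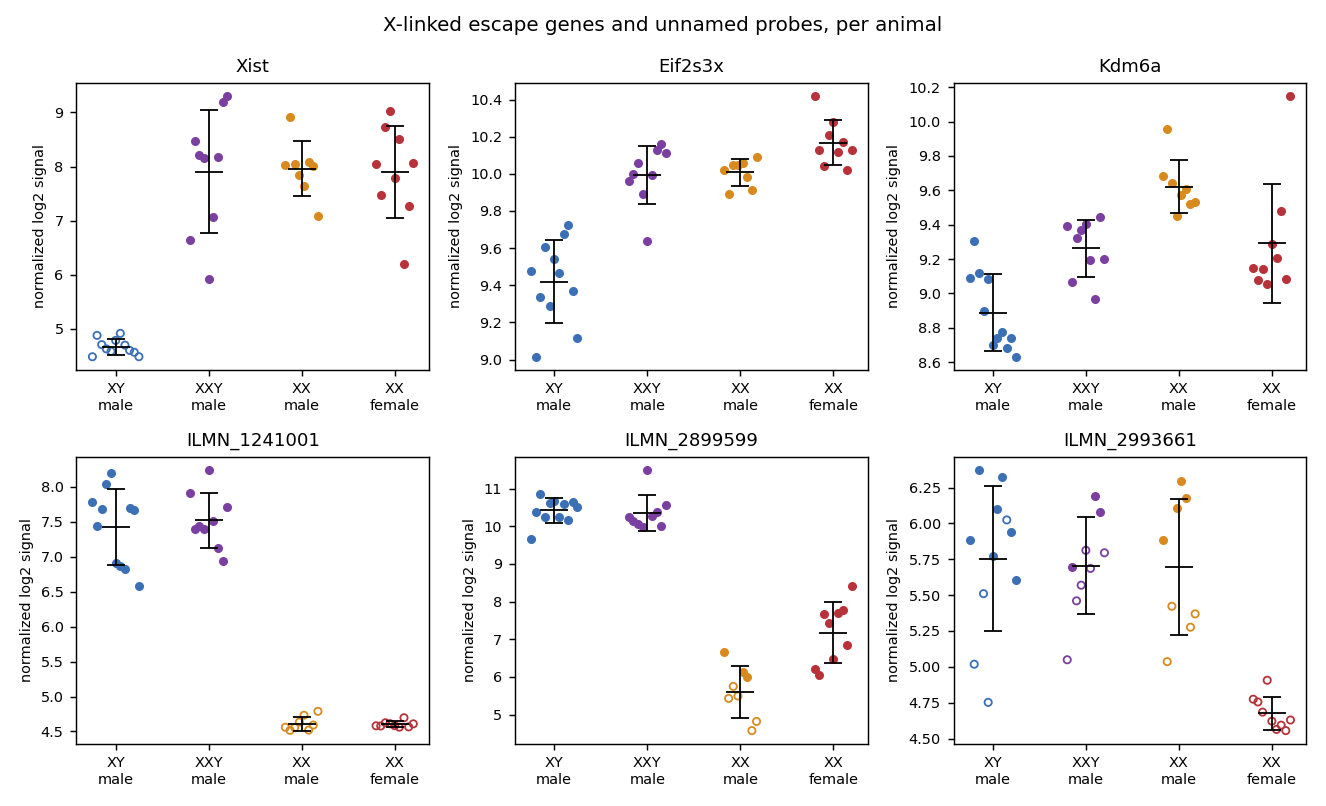
Normalized log2 signal of 3 X-linked genes of the escape list and 3 unnamed probes in each animal, by group. Filled points were detected, open points were not, and bars show the mean and SD. Xist is open in all XY males, ILMN_1241001 in all XX animals, and ILMN_2993661 in all 9 XX females.

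XX females against XY males compares the sexes, with the reservation that the sample codes of all 3 male groups, XY males included, carry the name of Sry, the testis-determining gene. Higher in females were 2 features and 3 were lower, with 498 at an unadjusted p under 0.05. Xist was at least 5.40-fold higher (adjusted p = 0.000102), and Eif2s3x was 1.63-fold higher (log2 0.70, SE 0.10, adjusted p = 0.00018), above the XY mean in all 9 females. Eif2s3x lost its call in a fit of these 2 groups alone (log2 0.69, adjusted p = 0.128) and with a replicate block (log2 0.57, adjusted p = 0.634). Xist lost it with the replicate block (log2 2.78, adjusted p = 0.283) and with the authors' log2 values (log2 3.44, adjusted p = 0.406). All 3 lower features were unnamed probes. ILMN_1241001 was at least 3.74-fold lower (adjusted p = 3.03e-13). ILMN_2899599 fell by 3.39 on the log2 scale (SE 0.34, adjusted p = 5.23e-08), with 7.18 ± 0.81 (SD, n = 9) in females and 10.4 ± 0.33 (SD, n = 11) in XY males. ILMN_2993661 was at least 1.17-fold lower (adjusted p = 5.27e-05), at 4.68 ± 0.12 (SD, n = 9) against 5.76 ± 0.51 (SD, n = 11). Kdm6a had a log2 of 0.62 (SE 0.13) and missed the threshold (adjusted p = 0.0736). Within the escape list, 6 of 7 differences were positive and 4 genes passed when adjusted over the list alone (Xist, Eif2s3x, Kdm6a and Pbdc1). As a set this list rose with both correlations (adjusted p = 7.86e-11 and 2.16e-06), with Xist, which the karyotype sets, in it.

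No named autosomal gene passed between XX females and XY males. Glucocorticoid and androgen responsive genes had 16 of 19 positive differences (median log2 0.41), among them Nfkbia at 0.66 (SE 0.24), Ddit4 at 0.51 (SE 0.22) and Cdkn1a at 0.88 (SE 0.39). Their adjusted p was 0.000188 with the preset and 0.770 with the estimated correlation. Ribosomal protein genes, with 49 of 56 positive, and oxidative phosphorylation genes, with 55 of 78, lay the same way (adjusted p = 0.000235 and 0.00308 at the preset correlation). With an estimated correlation their adjusted p was 0.797 and 0.853. Oligodendrocyte markers had 2 of 11 positive differences (adjusted p = 0.0152 and 0.797). Thalamic and septal markers had 0 of 8 positive differences, with Tcf7l2 at -1.10 (SE 0.49) and Ntng1 at -1.01 (SE 0.46), and adjusted p = 0.000733 and 0.770 in turn. Choroid plexus markers again had 0 of 8 positive differences (median log2 -0.91, adjusted p = 0.0143 and 0.797). The blood markers Hbb-bt at 1.25 (SE 0.52), Alas2 at 0.63 (SE 0.29) and Hba-a1 at 0.43 (SE 0.21) were all positive (adjusted p = 0.00262 and 0.768). Without the run term 207 features passed in this comparison. In labelled batch 2 alone 14 passed and in labelled batch 1 alone 1 passed.

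XX males against XY males compares sex chromosomes among animals with male gonads. Higher in XX males were 3 features and 2 were lower, with 615 at an unadjusted p under 0.05. Xist was at least 5.63-fold higher (adjusted p = 2.2e-06), Eif2s3x was 1.56-fold higher (log2 0.64, SE 0.10, adjusted p = 0.000642) in all 8 XX males (not past the threshold in a fit of these 2 groups alone, adjusted p = 0.0815), and ILMN_3123341 was at least 2.08-fold higher (adjusted p = 0.0028). ILMN_1241001 was at least 3.13-fold lower (adjusted p = 5.64e-18). ILMN_2899599, detected in 3 of the 8 XX males, was at least 21.9-fold lower, at 5.60 ± 0.68 (SD, n = 8) against 10.4 ± 0.33 (SD, n = 11) (adjusted p = 2.42e-12). With the probe kept for each, all 7 escape genes had positive differences and 5 passed when adjusted over the list alone (Xist, Eif2s3x, Kdm6a, Ddx3x and Bgn). Of probes not kept, one of Car5b lay at -0.09 (SE 0.15) and one of Kdm6a at 0.61 (SE 0.15). The escape list rose as a set with both correlations (adjusted p = 4.41e-10 and 3.36e-06), again with Xist in it. Oxidative phosphorylation genes had 9 of 78 positive differences and ribosomal protein genes 10 of 56, with adjusted p = 1.14e-05 and 0.00308 at the preset correlation. With an estimated correlation their adjusted p was 0.800 and 0.839. Endothelial genes had 7 of 8 positive differences, led by Pecam1 at 0.78 (SE 0.27) and Flt1 at 1.39 (SE 0.59), and lost their call likewise (adjusted p = 0.00703 and 0.770). Galanin, Gal, had a log2 of -1.09 (SE 0.42) among 13 neuropeptide genes, 2 of them positive (adjusted p = 0.012 and 0.770). Glucocorticoid and androgen responsive genes had 16 of 19 positive differences, as in XX females (adjusted p = 0.00308 and 0.770). The count was 134 without the run term and 2477 with array weights.

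XXY males against XX females compares animals that share 2 X chromosomes and differ in the Y chromosome and gonads. Higher in XXY males were 4 features, all unnamed, and 0 were lower, with 387 at an unadjusted p under 0.05. ILMN_1241001 was at least 3.99-fold higher (adjusted p = 7.27e-13), ILMN_2899599 was higher by a log2 of 3.34 (SE 0.36, adjusted p = 2.51e-07), and ILMN_2993661 was at least 1.13-fold higher (adjusted p = 0.000164). ILMN_3159435 was higher by 1.50 (SE 0.29, adjusted p = 0.0237). It lost its call in several alternatives, among them the fit of these 2 groups alone (log2 0.98, adjusted p = 1.00). Xist differed by a log2 of 0.25 (SE 0.45) and Eif2s3x by -0.12 (SE 0.11), and neither passed. Glucocorticoid and androgen responsive genes had 3 of 19 positive differences (median log2 -0.34), including Sgk1 at -0.58 (SE 0.26) and Cdkn1a at -0.97 (SE 0.41). Their adjusted p was 1.03e-05 with the preset and 0.770 with the estimated correlation. Oxidative phosphorylation genes, with 19 of 78 positive, and ribosomal protein genes, with 11 of 56, had adjusted p = 5.38e-05 and 0.000869 beside them. Both had 0.814 with an estimated correlation. Drd1 differed by -0.09 (SE 0.25) and Drd2 by 0.19 (SE 0.34).

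XXY males against XX males compares the presence of a Y chromosome among animals with male gonads and 2 X chromosomes. Higher in XXY males were 2 unnamed probes and 0 features were lower, with 590 at an unadjusted p under 0.05. ILMN_1241001 was at least 3.33-fold higher (adjusted p = 5.12e-18) and ILMN_2899599, detected in 3 of the 8 XX males, was at least 20.9-fold higher (adjusted p = 4.48e-12). Neuropeptide genes had 12 of 13 positive differences, with Nts at 1.24 (SE 0.52) and the vasopressin receptor gene Avpr1a at 0.74 (SE 0.27), and adjusted p = 0.00147 at the preset and 0.770 at the estimated correlation. Oxidative phosphorylation genes, with 67 of 78 positive, and ribosomal protein genes, with 47 of 56, lay the same way (adjusted p = 0.000763 and 0.000973). Their adjusted p with an estimated correlation was 0.839 and 0.814. All 3 lists lay on the negative side of the main component of variation within groups, with median correlations of -0.52, -0.71 and -0.66. Glucocorticoid and androgen responsive genes had 2 of 19 positive differences (adjusted p = 0.000303 and 0.770). Choroid plexus markers had 0 of 8 positive differences (median log2 -1.07, adjusted p = 0.00207 and 0.770). Among them were Ttr at -1.32 (SE 0.64) and Otx2 at -1.01 (SE 0.52), which did not pass singly (adjusted p = 0.689 for both). Without the run term 165 features passed, and with array weights 152.

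XX males against XX females compares gonadal sex with the same chromosomes, and here the letter and the group coincide for every animal. The difference therefore rests on the run effect as estimated in XY and XXY males. In those males the run is separated from the labelled batch only through the animals with both letters. ILMN_2993661 alone passed, at least 1.13-fold higher in XX males (adjusted p = 0.00522). It was detected in 0 of 9 XX females and in 4 of 8 XX males, 3 of 9 XXY males and 7 of 11 XY males. Its mean log2 was alike in the male groups, at 5.70 in XX males, 5.70 in XXY males and 5.76 in XY males. Of the XXY males 6 had both letters, and detection p-values of such merged columns may not match those of single arrays. There were 720 features at an unadjusted p under 0.05. Without the run term 2544 features passed, and with array weights 1964. The SE of this comparison was 1.77 times that of a model without the run term. Xist differed by 0.48 (SE 0.62) and Eif2s3x by -0.06 (SE 0.15). Glucocorticoid and androgen responsive genes had 9 of 19 positive differences and did not pass (adjusted p = 0.836). Oxidative phosphorylation genes had 12 of 78 and ribosomal protein genes 8 of 56 positive differences (adjusted p = 3.69e-06 and 3.09e-05). With an estimated correlation their adjusted p was 0.797 and 0.770.

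**Figure D3:**
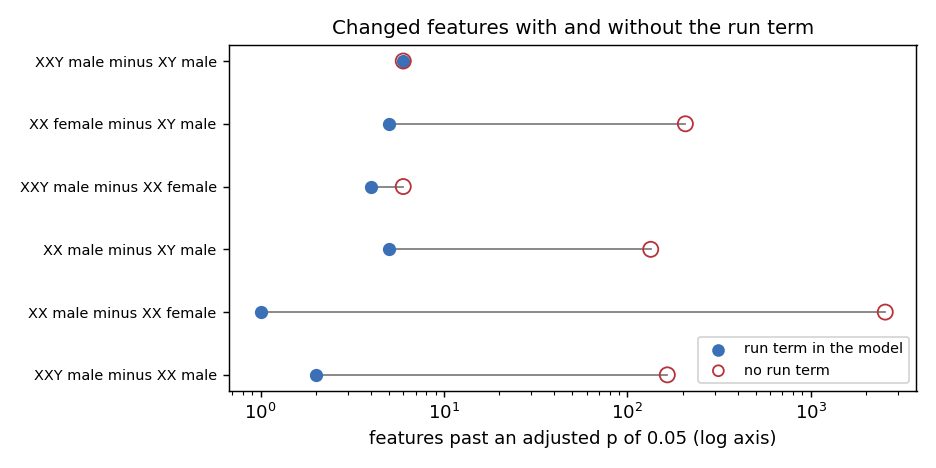
Number of features past an adjusted p of 0.05 in each comparison, on a log axis, with the run term in the model (filled) and without it (open). The count for XX male minus XX female goes from 1 with the term to 2544 without it.

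Over all 6 comparisons, 15 of the 25 lists passed at least once at the preset correlation, in 43 of 150 pairs of list and comparison. With an estimated correlation 3 pairs passed, the escape list in its 3 comparisons with XY males, and fry called 3 pairs, again of the escape list. For the other 40 pairs the estimated-correlation adjusted p lay between 0.768 and 0.853. The 10 lists that passed in no comparison were cholinergic and GABAergic interneuron markers, dopamine and monoamine metabolism, dopamine receptor signalling, sex steroid synthesis and receptors, GABA receptors and transport, astrocyte, mural and meningeal, and cortical neuron markers, and stress genes.

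In each comparison with XY males 2 of 285 X-linked and 0 of 8155 autosomal named genes changed, a higher share on the X chromosome (Fisher's exact test, two-sided, p = 0.00114, adjusted p = 0.00228 over 6 comparisons). The unnamed probes called, 4 for XXY males and 3 each for XX females and XX males, have no known chromosome and were left out of this share. The named genes called were Xist and Eif2s3x each time. Xist served as the label check and is set in advance by the karyotype, so only Eif2s3x adds to this share and the p-value overstates it. For XX females this share lost its call with a replicate block, where 0 X-linked genes passed (p = 1.00), and without the run term (p = 0.126), and for XX males without the run term (p = 0.293). In the other 3 comparisons no named X-linked or autosomal gene changed (exact p = 1.00).

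Feminization was addressed through the autosomal genes. Across 8155 autosomal genes, which are not independent replicates, the XXY male and XX female differences from XY males correlated at Pearson r = 0.32 and Spearman rho = 0.20, and 55.2% of genes had the same sign. Both differences share the XY males. With residuals permuted across animals, so that no group differed, the median r was 0.32 and the range over 95% of draws ran from -0.35 to 0.80. The covariance was 0.00994 against a median of 0.00979 in these draws, and 50 of 100 draws gave one as large (permutation p = 0.505). When separate random parts of the XY males served the 2 differences, the median r over 100 splits was -0.02, ranging from -0.41 to 0.33. No named autosomal gene passed in either comparison, so there was no overlap of called autosomal genes to weigh. Of the called features, 4 unnamed probes for XXY males and 3 for XX females have no known chromosome and were left out here.

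A score over the 100 autosomal genes that best separated random parts of the XX females and XY males, read in the animals left out, placed XX females 0.61 above XY males. The adjustment for the run alone moves this score, since permuted residuals gave a median of 0.40 (permutation p = 0.366). XXY males lay at -0.03 from XY males, against 0.00046 in permuted residuals (permutation p = 0.851), and XX males at -0.31, against -0.33 (permutation p = 0.941). Adjusted over the 5 differences computed, these p-values were 0.915, 0.941 and 0.941. With the run term the score therefore did not separate XX females from XY males beyond chance. Without the run term it did, at 0.73 against a median of -0.0035 in permuted residuals (permutation p = 0.0099, the smallest that 100 draws give), but the letter then enters the score, as all XX females had letter b.

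**Figure D4:**
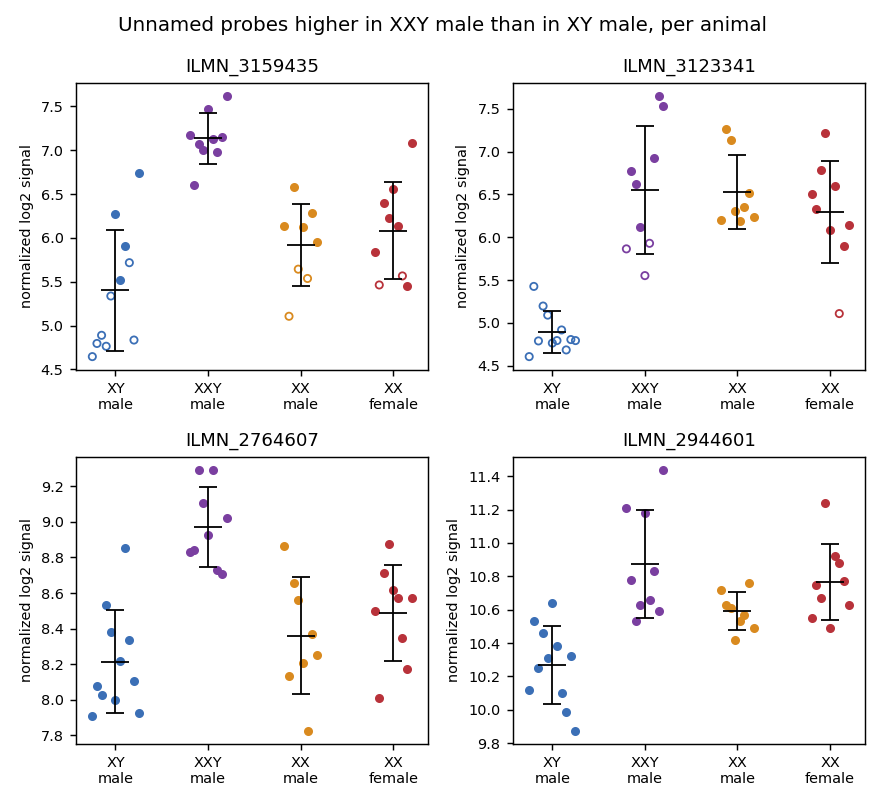
Normalized log2 signal of the 4 unnamed probes that were higher in XXY males than in XY males, in each animal by group. Filled points were detected, open points were not, and bars show the mean and SD. ILMN_2764607 averages 8.97 in XXY males and 8.21 in XY males.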

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

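The tests on gene span, on the 2 unnamed probes, on a neighbouring region and on the genotype group were chosen after their values were seen. Of 36 tests of an extreme animal (12 quantities in the 3 groups of 8 or 9 animals), 3 stood out, and chance alone gives about 1 in 20. ILMN_2899599 had a log2 of 11.5 in XXY male replicate 5, with the next XXY male at 10.6. ILMN_1241001 had 4.70 in XX female replicate 7, still undetected, with the next at 4.62. The same female lay at -66.2 on the first principal component of the residuals, with the next XX female at -9.61.

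That component held 45.3% of the variance left within groups, and 60% of features correlated with it above 0.5 in size. Ribosomal protein and oxidative phosphorylation genes lay on its negative side (median correlations -0.66 and -0.71), and striatal projection neuron, astrocyte and endothelial markers on its positive side (0.72, 0.72 and 0.75). Tissue from a neighbouring region in place of striatum was taken not to lower astrocyte and endothelial genes along with projection neuron genes. This does not cover choroid plexus or ependyma, whose markers lay mostly on the negative side (median correlations -0.31 and -0.40, 2 of 8 positive in each). The smaller of the astrocyte and endothelial medians was 0.716, but members went both ways. Astrocyte markers ran from -0.79 to 0.93, with 10 of 12 positive, and endothelial markers from -0.70 to 0.91, with 7 of 8 positive. Tissue from a neighbouring region therefore stays open. Gene span correlated with a gene's place on the component at a Spearman rho of 0.347 across genes. RNA integrity or transcript length could give this, but gene span measures neither. The lists on the positive and negative sides also differ in kind, so a change of tissue could give it too. The test does not tell these explanations apart. Genotype group explained 6.89% of the component beyond run and batch (permutation p = 0.53), which does not decide the matter.

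The 2544 features called between XX males and XX females without a run term were weighed against the run and the gonads. In XY and XXY males alone, 92.0% of them had a b-minus-a difference in the direction of XX female minus XX male, as the array run would give. Run and labelled batch separate in these males only through the animals with both letters, so batch may enter this share. Among letter b animals, 69.0% had an XX female minus XY male difference in that direction. Among letter a animals, 58.9% had an XY male minus XX male difference in that direction, with equal gonads and shared XX males. The same XX females enter both sides of that share, and it falls between the limits set in advance, so a contribution of gonadal sex cannot be told apart from the run. Of these features 1 passed with the run term.

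Chance was weighed by regrouping the animals of each comparison in 100 ways, the real one included. As many features as the real count came from 1 grouping for XXY males against XY males (6 features, 1 in the highest other grouping) and 1 for XX females against XY males (5 and 1). The number was 2 for XX males against XY males (5 and 21), 3 for XXY males against XX females (4 and 87), 2 for XXY males against XX males (2 and 2) and 3 for XX males against XX females (1 and 1). Each share was under 0.05, without adjustment over the 6 comparisons. Regrouping mixes the letters between groups, while all XX females had letter b and all XX males letter a. For comparisons with XX males or XX females the reference thus has another design than the data, and chance is not excluded. For XXY males against XY males, which both held both letters, no other grouping reached the 6 features. These include Xist, which the karyotype sets in advance, so the count does not bear on the unnamed probes singly. With permuted residuals, where no group differs, 5 of 100 draws gave calls in this comparison, with up to 3073 features. Groupings with 87 and 21 features, several times the real count, were rare. In each of these 2 comparisons 96 of the 99 other groupings gave none. Such counts do not by themselves show a structure of the samples. The first residual component was not shown to be their source, since 19 and 14 of the 99 other groupings explained as much of it.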

How the results depend on the processing

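The factor of 3 letter levels, the removal of 2 animals and the residual component were added after seeing the data, as was the score over 100 autosomal genes. Counts of changed features are given below in the order XXY−XY, XXF−XY, XXY−XXF, XXM−XY, XXM−XXF, XXY−XXM (M male, F female), for which the main counts were 6, 5, 4, 5, 1 and 2. The cause of each change was not tested unless stated. With probes detected in every animal the counts were 3, 1, 0, 1, 0 and 0, since features absent from a group leave the test. Without the run term XXF−XY had 207, XXM−XY 134, XXM−XXF 2544 and XXY−XXM 165, and without run and batch terms 60, 178, 2507 and 121; without the batch term XXF−XY had 8. Array weights gave 26, 10, 2477, 1964 and 152 from XXF−XY on. The residual component as a covariate gave 207, 251, 1387, 1646 and 1054. That component is orthogonal to the groups by construction and so narrows the errors without correcting the differences. With permuted residuals, where nothing differs, it called features in 49 to 60 of 100 draws and array weights in 14 to 23, against 1 to 5 for the main model, whose highest such draws still held 3073 features for XXY−XY and 3009 for XXY−XXM. The counts with array weights for XXM−XY and XXM−XXF were above the highest of these draws (1320 and 1389). Permuting residuals across all animals removes any difference in spread between groups, to which array weights respond. These draws therefore cannot show that the larger counts are real. With fewer animals the counts moved both ways. Letter a alone, with 2 XXY males, gave 0 for XXY−XY. Letter b alone gave 4 for XXF−XY. It holds a single XXY male, so its counts of 1 for XXY−XY and 5 for XXY−XXF take their spread from the other groups and test nothing. Labelled batch 1 gave 2, 1, 2, 3 and 0 for the first 5 comparisons, and labelled batch 2 gave 2, 14, 2, 2 and 0. The authors' log2 values gave 2 for XXF−XY and 1 for XXY−XXF.

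Leaving out each animal in turn gave 6 to 6, 5 to 6, 3 to 4, 5 to 5, 1 to 1 and 2 to 4 features. XXY−XXM rose to 4 without XXY male replicate 4. Of the 23 pairs of called feature and comparison, 22 passed with quantile normalization without background correction, 22 without the filter, 22 without the run term, 23 without the batch term, and 7 of the 10 measured in the authors' log2 values. In fits of the 2 compared groups alone Eif2s3x missed the threshold for XXF−XY (adjusted p = 0.128) and XXM−XY (0.0815). Single features were followed in the alternatives that could fit their comparison, but not in the fits leaving out 1 animal. No called feature reversed its direction in those followed. Among these features over the alternatives followed, 329 alternative values kept their side of the threshold and 58 did not.

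Replicate numbers are shared by the groups, and the 48 pairs of animals with the same number had a median residual correlation of -0.02, with 20 above 0.1, so the numbers do not pair animals. With a replicate block the counts were 5, 3, 3, 5, 1 and 2, 19 of the 23 pairs passed, and 38 list pairs passed. For XXF−XY the block left 0 X-linked genes called (exact p = 1), with Xist at adjusted p = 0.283 and Eif2s3x at 0.634; for XXY−XY and XXM−XY the X-linked share kept p = 0.00114. The autosomal correlation was 0.68 under the block, against 0.57 in permuted residuals. For list pairs, 43 in the main setting became 3 with an estimated correlation, 3 with fry, 20 of 75 with the authors' log2 values and 18 without the run term. Without the run term the X-linked share lost its call for XXF−XY (p = 0.126) and XXM−XY (p = 0.293). The autosomal correlation turned to -0.0198 with XY males split, because the shared controls are then removed. The XXY score turned from -0.03 to 0.0489 with the authors' log2 values, 0.0482 without the run term, 0.0139 without the batch term and 0.391 under the replicate block, with permutation p between 0.604 and 0.851 throughout. The XX female score was 0.73 without the run term (permutation p = 0.0099), against 0.61 (0.366) with it.

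Not run were normalization within each letter, a fit over single arrays with animals as a block and a chip block, since merged columns cannot be parted and no chip is given. Letter a alone holds no XX females and letter b alone no XX males, and a fit of XX males and XX females alone has letter and group coincide. The authors' log2 values gave no XX male comparison. Dim probes limit the calls, as unnamed probes near background and Uty show.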

Other observations

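The 4 unnamed probes higher in XXY males than in XY males fell into different patterns over the groups. ILMN_3123341 followed Xist, detected in 8 of 9 XX females, 8 of 8 XX males, 6 of 9 XXY males and 0 of 11 XY males. Its mean log2 was 6.30, 6.52, 6.55 and 4.90 in the same order. ILMN_2944601 had a log2 of 10.9 in XXY males, 10.8 in XX females, 10.6 in XX males and 10.3 in XY males. ILMN_2993661, which was not among these, was undetected in all 9 XX females and detected in part of each group with male gonads. The 278 X-linked genes outside the escape list had a median log2 difference of 0.0084 between XXY and XY males, against -0.0020 for autosomal genes. The difference of 0.0104 exceeded 65 of 99 other groupings of the animals, where the highest gave 0.0855, so a shift of these genes with the dose of the second X chromosome did not stand out from chance.

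The tests of the next pattern were chosen after seeing the values. ILMN_2764607 and ILMN_3159435 were highest in XXY males. If the number of X chromosomes set their level, XXY males would equal XX animals. XXY males exceeded them by up to 3.54 SE for ILMN_2764607 and 5.17 SE for ILMN_3159435, but both probes were taken up because they were highest in XXY males, so this decides nothing. An effect of an additional sex chromosome would leave XX animals level with XY males. For ILMN_3159435 the XX males exceeded XY males by 3.50 SE, while XX females lay 1.01 SE above XY males. This probe was detected in 4 of 11 XY males, all with letter b, and in 5 of 8 XX males, all with letter a. The XY males with letter a alone were undetected, at 4.65 to 5.34, against a mean of 5.92 in XX males. By the rule written for this test the 3.50 SE goes against an effect of an additional sex chromosome. It rests on values near background and XX females did not share it, so it is not taken to decide the matter. For ILMN_2764607 the XX animals lay within 1.23 SE of XY males, and the explanation stays open there. Erdr1, the only pseudoautosomal gene measured, does not settle it. XX males were above XY males by a log2 of 1.45 (SE 0.46) and XX females by 0.45 (SE 0.48), and XXY males lay at -0.22 (SE 0.46) from XX males and 0.78 (SE 0.50) from XX females.

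Preset-correlation list calls were also made on permuted residuals, where no group differs. A median of 32 of the 150 pairs passed there, with up to 57 in 100 draws, against 43 observed. With an estimated correlation 5 of the 100 draws had any call.

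Taken as deposited, the log2 table would give 7957 of 9078 features changed between XX males and XY males and 5 between XXY males and XY males.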
